A study of Mus musculus with 7 samples.

How the data were processed

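Gene expression was measured on 7 arrays, 1 per sample, with 3 samples of high avidity and 4 of low avidity CD8+ T cells. Groups and replicate numbers were taken from the sample titles. The deposited table holds log2 expression values, 1 column per sample and 115830 rows, made by the authors with RMA (background correction, quantile normalization and median polish of probes) in Partek, with the mouse build mm9, per the submitters' processing notes. Versions, filters and the level of probe summary are not given in the sources used here. The log2 scale was taken from the RMA step and the range of the values. No scanner intensities were used here, so scale and centring were not checked against them, and no detection p-values were at hand. The median of all rows was 4.31, 4.31 and 4.32 log2 in high avidity 1, 2 and 3, and 4.23, 4.29, 4.29 and 4.25 log2 in low avidity 1, 2, 3 and 4.

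Rows were named through the platform annotation. Of the 115830 rows, 25539 had 1 gene symbol, 2300 had several and 87991 were not listed with a gene, so that genes found only on rows with several symbols, such as Ctla4, are not reported. Symbols were updated through the gene identifier to the RefSeq annotation of GRCm38.p6 for 24941 rows and kept as listed for 598. Because that assembly is not mm9, only its names were used, and no coordinates are given. This gave 20259 genes, of which 3109 had several rows. The row with the highest mean over the 7 samples stood for a gene. Rows of a gene did not always move together: of the 117 genes followed by name across the settings, 21 had several rows and 7 had a row with the opposite sign, among them Cd69, Eomes, Irf4 and Txnip. Variable segments of the T cell receptor have near-identical copies that an array probe may not tell apart, so a segment's name is uncertain.

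The 25% of genes with the lowest mean, under 3.97 log2, were left out, leaving 15194 genes. As a guide to background, 862 olfactory receptor genes had a median level of 3.65 log2, and 95% of them lay under 5.03. Where a group lies in that range, as for Trdv2-2, 6230415J03Rik, Trav14d-3-dv8, Trav12d-2, Bcl6, Fasl, Cxcr5, Ccl3, Tgfbr3 and Bhlhe40 among others, the size of a difference is uncertain. Low minus high avidity differences were fitted with limma 3.58.1 in R 4.3.3 (lmFit and eBayes), with all 7 samples, no covariates and Benjamini-Hochberg adjustment at 0.05. The labels give no batch, so none could be tested. Nothing states whether the samples came from separate mice or pools, so p-values measure only the spread between these samples, which may be technical. The number of arrays limits the precision.

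Gene lists, written from textbook knowledge, were tested with camera at a preset correlation of 0.01 between genes, and adjusted over the 35 lists tested out of 36. They cover pro-apoptotic and anti-apoptotic genes, death receptors, p53 targets, cytotoxic molecules, cytokines, cytokine receptors, costimulatory and inhibitory receptors, early response and negative regulators of T cell receptor signalling, naive and memory T cells, effector transcription factors, homing molecules, receptor variable segments, mitosis, DNA replication, glycolysis, cholesterol synthesis, oxidative phosphorylation, ribosomal proteins, both interferon responses, NF-kappaB, Myc-linked growth and the unfolded protein response. Markers of CD8 T cells, CD4 and regulatory T cells, B cells, macrophages, dendritic cells, NK cells, neutrophils, red cells and platelets, and stroma were also listed. Sex-linked genes, with 2 genes left by the filter, were not tested as a list. The estimated correlation between genes and fry served as alternatives. Members of each list were also adjusted over the list alone.

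Named genes followed a rule. In each direction it took the 10 genes with the largest difference among those that passed with groups that did not overlap, filled with the smallest p where fewer passed, and passed over predicted genes and small RNAs. It added up to 4 members of each list with the smallest p, and a preset set of apoptosis, costimulation and effector genes. The groups, tests, lists, rule and alternatives were fixed before the data were examined. The alternatives were no filter or a filter on 50% of genes, a second quantile normalization, median centring, the mean of a gene's rows, every row on its own, an intensity trend, robust eBayes, array weights, the replicate number as a block, and leaving out each sample. Genes named outside the rule, 6230415J03Rik, Irf4, Trav16, Cdk1, Tpx2, Birc5, Pcna, S100a4, Rasgrp1, Muc13, Angpt1, Ctsg and Prtn3, were chosen after their values were seen. A list of blood progenitor genes and a list of follicular helper genes were written after single genes had been seen and before either list was tested; 3 of the 22 and 4 of the 10 members in the fit also stand in the lists above.

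The scripts were tested on simulated data. Over 15194 simulated genes with the spread of the real samples, limma recovered 62% of 100 genes changed 2-fold and 90% of 100 changed 4-fold in the low against high avidity comparison, with 9 false calls. Planting that many changed genes loosens the adjusted threshold, so these shares do not carry over to the real comparison. There, Bcl6 at 1.05 log2 (SE 0.13) did not pass (limma, adjusted p = 0.18). With no change simulated, 0 genes and 0 lists were called. The simulated genes were independent of each other, unlike the real mitosis genes, whose estimated correlation was 0.90. The 0 lists therefore do not show how often camera at the preset correlation calls correlated lists by chance. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.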

Results

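Array profiles were recorded for CD8+ T cells from T cell receptor transgenic donors whose receptors bind a tumour antigen with high or low avidity. The cells had been transferred into tumour-bearing neu-N mice, which carry the rat HER-2/neu gene as a transgene. The recipients had received Cy at 100 mg/kg and a vaccine of 3000000 3T3neuGM cells, and 3 days after transfer the T cells were sorted from lymph nodes draining the tumour. There were 3 high avidity and 4 low avidity samples, and values are RMA expression on the log2 scale. The design asks how the low avidity cells differ from the high avidity cells at this time, and the title of the series points to apoptosis and costimulation.

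The 4 low avidity samples resembled each other, with correlations across genes of 0.970 to 0.983 (genes are not independent replicates). The 3 high avidity samples did not form such a group: correlations within them ran from 0.941 to 0.970, and correlations between the groups from 0.952 to 0.968. High avidity 1 stood apart. On the component with 33.4% of the variance it lay at -24.6, against 27.5 and 33.9 for high avidity 2 and 3 and -11.4 to -7.34 for the low avidity samples.

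**Figure D1:**
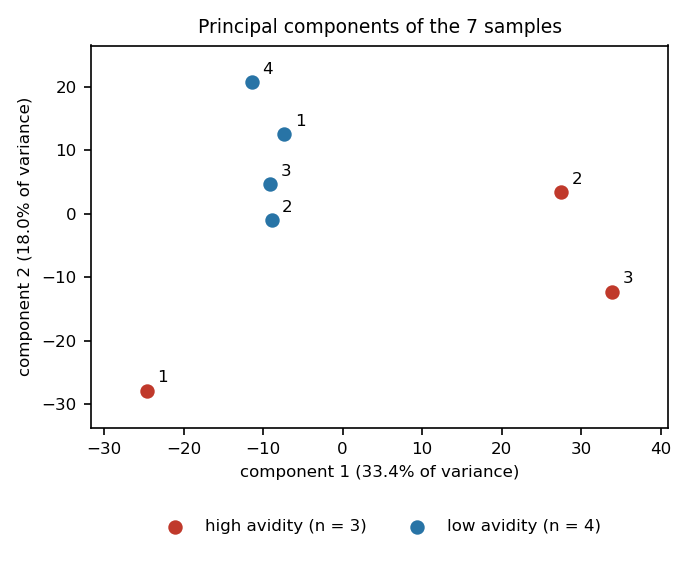
Principal components of the 15194 genes, with 1 point per sample, coloured by group and numbered by replicate; axes are component scores, with 33.4% and 18.0% of the variance. High avidity 1 (-24.6 on component 1) lies apart from high avidity 2 and 3 (27.5 and 33.9).

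Segments of the T cell receptor gave the clearest differences between the groups. The donors carried receptor transgenes, and since the labels do not give the segments these use, the values could not be set against them. Trav7n-4, a variable segment of the alpha chain (row 6828214), was higher in low avidity cells by 3.59 log2 (SE 0.29, 95% interval 2.91 to 4.27), or 12.0-fold, with 8.94 ± 0.23 (SD, n = 4) against 5.36 ± 0.65 (SD, n = 3; limma, adjusted p = 0.0156). Trdv2-2, a delta chain segment whose locus lies within that of the alpha chain (row 6819096), fell by 2.04 log2, with 4.49 ± 0.11 (SD, n = 4), within the range of the background guide, against 6.53 ± 0.29 (SD, n = 3; limma, adjusted p = 0.0156). The third gene that passed, the predicted transcript 6230415J03Rik (row 6959986), was at 5.40 ± 0.20 (SD, n = 4) in low avidity cells and at 3.75 ± 0.13 (SD, n = 3), near background, in high avidity cells, a difference of 1.65 log2 (limma, adjusted p = 0.0156). All 3 genes separated every low avidity sample from every high avidity sample. The list of 9 receptor segments, 8 of the alpha and 1 of the beta chain, had a mean difference of 0.90 log2 with 7 members higher (camera, adjusted p = 0.000234), or adjusted p = 0.5 with an estimated correlation. Adjusted over the list alone, 3 of the 9 rose, Trav7n-4, Trav14d-3-dv8 (1.65) and Trav12d-2 (0.90), against 1 over all genes tested. The last pair lay within the range of the background guide in high avidity cells.

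Of the 15194 genes, 3 passed limma at an adjusted p under 0.05, 2 higher and 1 lower in low avidity cells, and 1272 had an unadjusted p under 0.05 (694 higher, 578 lower). The groups did not overlap for 1454 genes, or 9.57%, where chance gives 5.71%. The count changed when single samples were left out, while the differences of the 3 genes stayed at 3.25 to 3.90 log2 (Trav7n-4), -2.20 to -1.92 (Trdv2-2) and 1.59 to 1.72 (6230415J03Rik). It was 0 without high avidity 2 or without any of low avidity 1, 2, 3 or 4 (880 to 1369 genes at an unadjusted p under 0.05), 1 without high avidity 3, and 93 without high avidity 1 (26 higher, 67 lower).

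Genes of naive and memory T cells lay higher in low avidity cells, by a mean of 0.34 log2 over 26 genes, 19 of them higher (camera, adjusted p = 3.61e-05), or adjusted p = 0.661 with an estimated correlation. Adjusted over the list alone, 2 of the 26 rose and 0 fell, against 0 over all genes tested. These were Bcl6, a transcriptional repressor of memory and follicular helper cells (1.05 log2, SE 0.13, with high avidity cells in the range of the background guide), and Eomes, a T-box factor of effector and memory CD8 T cells (0.90 log2, SE 0.13), each higher in every low avidity sample, though 1 of the 2 dimmer rows of Eomes had the opposite sign. Myb differed by 1.08 log2 and Il7r, the receptor of interleukin 7, by 0.75 log2, without passing, and Ccr7 by -0.55. High avidity 1 lay with the low avidity samples for this list, at 0.20 above the mean of all samples, where high avidity 2 and 3 lay at -0.40 and -0.38 and the low avidity samples at 0.11 to 0.23. Without it the mean difference was 0.53 log2 (camera, adjusted p = 8.14e-10, or adjusted p = 0.0657 with an estimated correlation), and Bcl6, Eomes and Myb passed over all genes.

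Among 21 effector transcription factors (camera, adjusted p = 0.273), 3 passed adjusted over the list alone and 0 over all genes tested. Ikzf2, which encodes Helios, was higher by 1.38 log2 (SE 0.19), with 7.65 ± 0.36 (SD, n = 4) against 6.27 ± 0.11 (SD, n = 3), Eomes was higher as above, and Bhlhe40 was lower (-0.60 log2, SE 0.15). Tbx21, which encodes T-bet, differed by -0.24. Among 26 chemokine receptors and homing molecules (mean -0.06 log2, camera, adjusted p = 0.621), 2 fell adjusted over the list alone and 0 over all genes tested. Cxcr3, a receptor that guides T cells to inflamed tissue, differed by -1.33 log2 (SE 0.19), with 6.81 ± 0.35 (SD, n = 4) against 8.14 ± 0.12 (SD, n = 3), and Itgb1, the integrin beta 1 chain, by -1.05 (SE 0.14). The test of the homing list turned its direction without high avidity 1 (mean -0.012). Cxcr5, the homing receptor of follicular cells, differed by 1.36 log2 and did not pass.

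**Figure D2:**
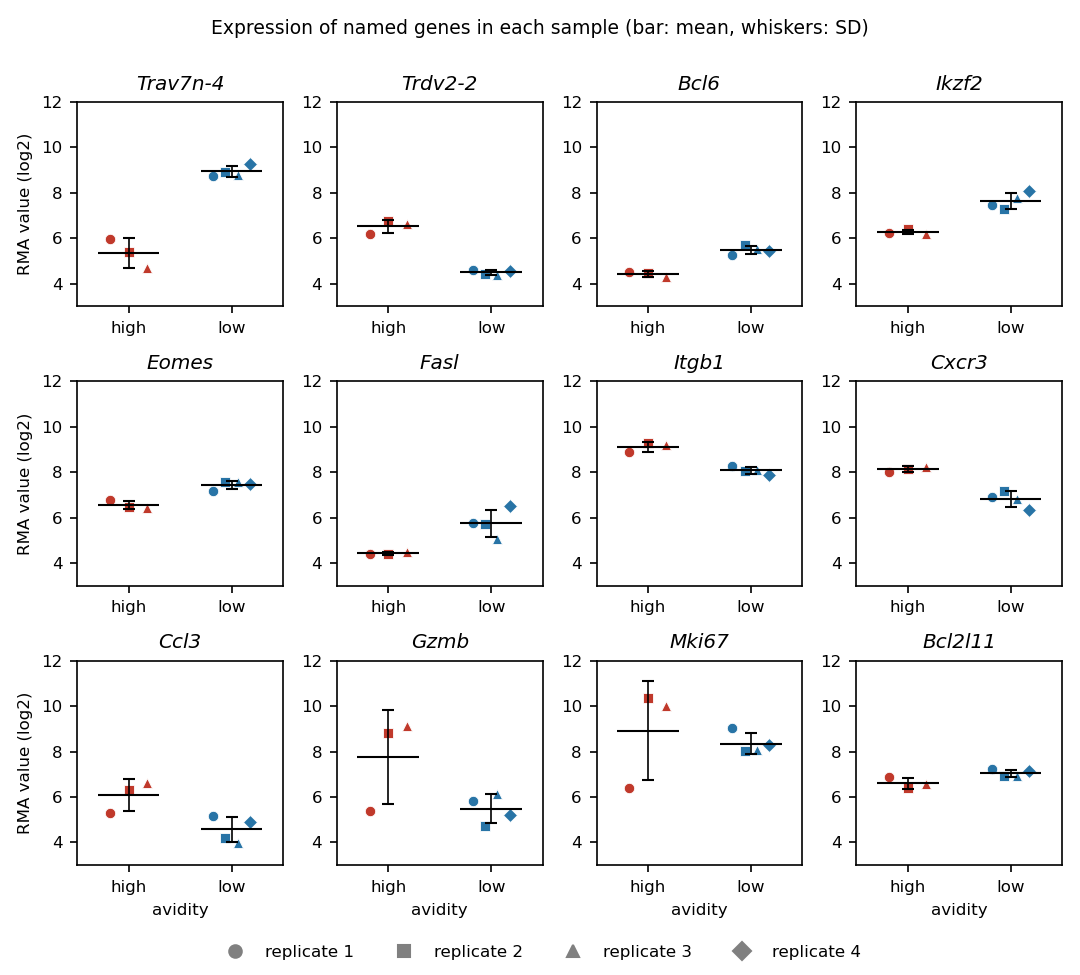
RMA values (log2) of named genes in each sample, by avidity group, with bars at the mean and whiskers of 1 SD (n = 3 high, n = 4 low). Trav7n-4 and Trdv2-2 passed the test over all genes; Gzmb and Mki67 in high avidity 1 lie at 5.38 and 6.40, far below high avidity 2 and 3.

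The rule for named genes took 2 genes that passed and filled the rest by the smallest p, so that the following did not pass, with adjusted p of 0.18 to 0.295 (limma). Besides Bcl6, Eomes and Ikzf2, those higher in low avidity cells were Slain1os (0.89 log2), Cxxc5 (0.66), Mettl21c (1.08), Sh3bp5 (0.68), Rhno1 (0.55) and Zfp595 (0.91). Besides Itgb1 and Cxcr3, those lower were Uqcr11, a subunit of respiratory complex III (-1.11 log2), Jaml, an adhesion molecule of T cells (-0.94), Spata5l1 (-0.95), Kbtbd7 (-0.80), Ldhb, a lactate dehydrogenase subunit (-0.80), Olfr574 (-0.65) and Rangap1 (-0.50). Of these, Slain1os, Itgb1, Uqcr11, Jaml and Kbtbd7 passed without high avidity 1 (adjusted p of 0.0409 to 0.049). A second, dimmer row of Spata5l1 had the opposite sign, and Ldhb lay near background.

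Cell cycle genes lay lower in low avidity cells, and differed most between the high avidity samples. All 41 mitosis genes were lower, with a mean of -0.70 log2 (camera, adjusted p = 8.26e-06), or adjusted p = 0.701 with an estimated correlation, and 37 of 39 DNA replication genes were lower, with a mean of -0.37 log2 (camera, adjusted p = 0.000395), or adjusted p = 0.701 with an estimated correlation. Neither list had a gene that passed, over all genes tested or adjusted over the list alone. Among mitosis genes, Racgap1 differed by -0.88 log2, Cdc25c by -0.99, Kif2c by -0.96 and Ect2 by -0.71, and among replication genes Cdc45 differed by -0.96, Gins3 by -0.41, Rfc5 by -0.31 and Pold1 by -0.28. The mitosis list lay at -1.03 log2 from the mean of all samples in high avidity 1, at 1.14 and 1.08 in high avidity 2 and 3, and at -0.59 to 0.16 in the low avidity samples. Mki67, the proliferation marker, was at 6.40 in high avidity 1, at 10.34 in high avidity 2 and close to that in high avidity 3, and at 8.35 ± 0.46 (SD, n = 4) in low avidity cells. Without high avidity 1 the mean of the mitosis list was -1.41 log2 (camera, adjusted p = 4.04e-34, or adjusted p = 0.181 with an estimated correlation), and 11 of its genes and 9 replication genes fell over all genes, among them Cdk1 (-1.90), Tpx2 (-1.77), Birc5 (-1.69), Cdc45 (-1.33) and Pcna (-0.81). Without high avidity 2 the mitosis list had a mean of -0.33 log2 (adjusted p = 0.0501) and the replication list -0.11 (adjusted p = 0.499), and without high avidity 3 the replication list had -0.21 (adjusted p = 0.0654).

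**Figure D3:**
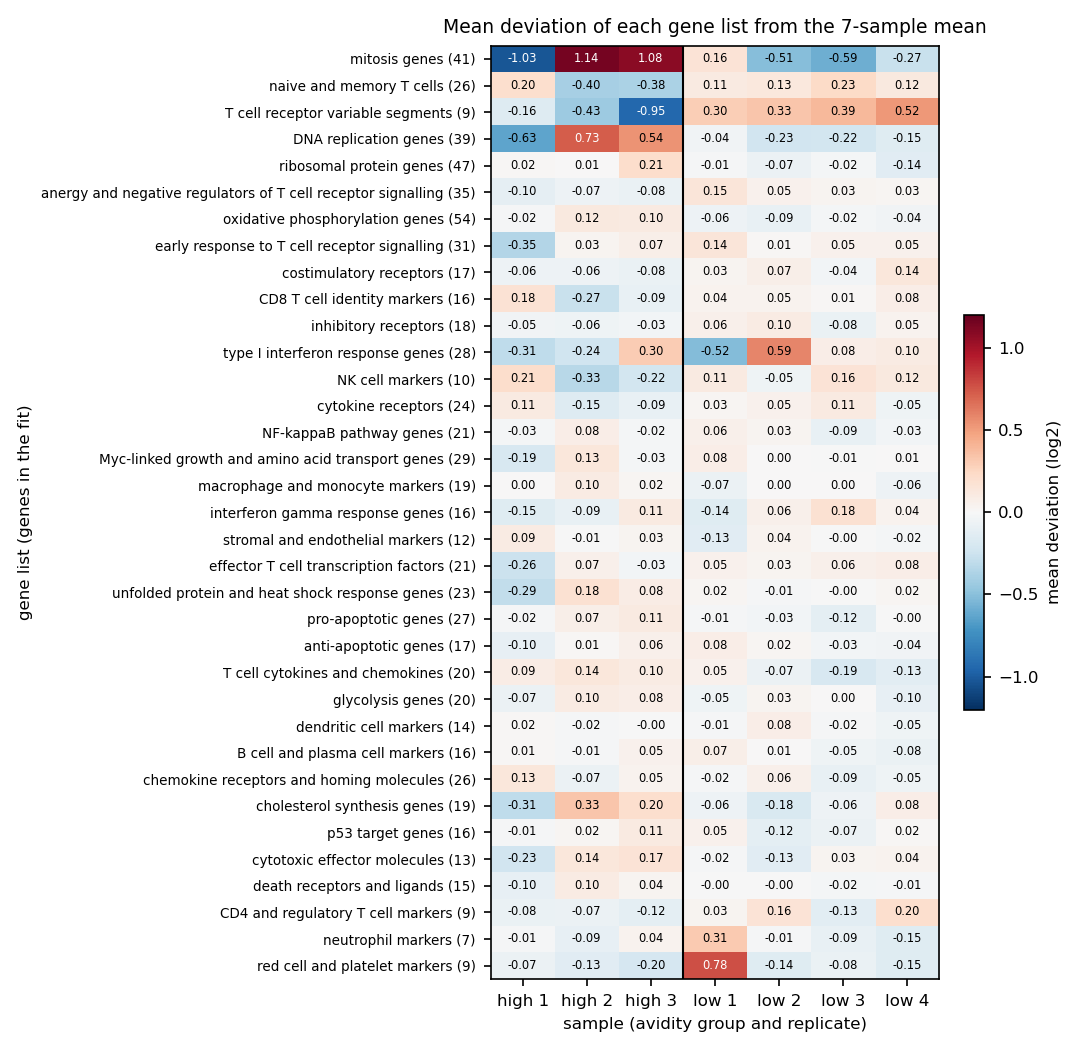
Mean deviation (log2) of each of the 35 gene lists (vertical axis, number of genes in parentheses) from the mean of the 7 samples, by sample (horizontal axis); red is above and blue below the mean. The mitosis list lies at -1.03 in high avidity 1 against 1.14 and 1.08 in high avidity 2 and 3.

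Effector molecules differed gene by gene. The 13 cytotoxic molecules had a mean of -0.05 and a median of 0.02 log2 with the test on the higher side (camera, adjusted p = 0.835), and the test turned under a second quantile normalization (mean -0.09). Adjusted over the list alone, 2 rose, against 0 over all genes tested: Fasl, the ligand of the death receptor Fas (1.32 log2, SE 0.30, at 4.43 ± 0.06 (SD, n = 3) in high avidity cells, within the range of the background guide), and Ctsc, a protease that activates granzymes (1.03 log2, SE 0.22). Gzmb, which encodes granzyme B, differed by -2.29 log2 (SE 0.88) and did not pass, being at 5.38 in high avidity 1, at 8.80 and 9.11 in high avidity 2 and 3, and at 5.48 ± 0.64 (SD, n = 4) in low avidity cells. Without high avidity 1 it fell by 3.48 log2 (limma, adjusted p = 0.0409). Prf1, which encodes perforin, differed by -0.20. The 20 cytokines and chemokines had a mean of -0.19 log2 (camera, adjusted p = 0.583) with 0 passing over either set: Ccl3 differed by -1.51, Ifng by -0.99, Tnf by -0.57, Lta by -0.40, Tnfsf8 by 0.49 and Il2 by -0.07, the last near background. Leaving out each sample, Ifng ran from -1.48 without high avidity 1 to -0.41 without high avidity 2, and Tnf from -1.01 to -0.12 without the same samples. Of 24 cytokine receptors (mean 0.08 log2, camera, adjusted p = 0.0988), Tgfbr3 rose (0.51) and Il18r1 fell (-0.86) adjusted over the list alone, 0 passed over all genes, and Il2ra differed by -0.68. Without high avidity 1 this list was called (mean 0.15, camera, adjusted p = 0.00833, or adjusted p = 0.168 with an estimated correlation). It was also called with no filter (adjusted p = 0.0316) and with array weights (adjusted p = 0.0349). Over leaving out each sample the mean of this list ran from 0.024 to 0.15 (camera, adjusted p up to 0.556). An estimated correlation over all samples gave adjusted p = 0.701.

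No apoptosis list was called. The 27 pro-apoptotic genes had a mean of -0.10 log2 (10 higher, 17 lower; camera, adjusted p = 0.58), and 0 passed over all genes or adjusted over the list alone. Bcl2l11, which encodes the BH3-only killer Bim, differed by 0.44 log2 (SE 0.14, 95% interval 0.12 to 0.77), with 7.05 ± 0.15 (SD, n = 4) against 6.61 ± 0.24 (SD, n = 3; limma, adjusted p = 0.489), higher in all 4 low avidity samples. Txnip differed by 0.41 (its second row had the opposite sign), Bnip3 by -0.25 and Pdcd5 by -0.24. The 17 anti-apoptotic genes had a mean of 0.015 log2 (camera, adjusted p = 0.58). Birc3, an inhibitor of apoptosis induced by NF-kappaB, was higher by 0.69 log2 (SE 0.12) and passed adjusted over the list alone, and 0 passed over all genes. Birc5, which also stands in the mitosis list, differed by -0.81, and by -1.69 without high avidity 1 (limma, adjusted p = 0.0409). Bcl2 differed by 0.72 log2 (SE 0.34), with high avidity 1 at 7.80, high avidity 2 and 3 at 6.49 and 6.48 and low avidity cells at 7.64 ± 0.30 (SD, n = 4), Mcl1 by 0.09, Pim2 by -0.39 and Bcl2l1 by -0.03, the last turning to 0.017 when samples were centred on their median. Of the 15 death receptors and ligands (mean -0.02, camera, adjusted p = 0.932), Fasl rose adjusted over the list alone, and Fas differed by 0.28. The 16 p53 targets had a mean of -0.07 log2 (camera, adjusted p = 0.692), with 0 passing over either set.

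The 17 costimulatory receptors left by the filter were not called as a list. They had a mean of 0.12 log2, 13 of them higher (camera, adjusted p = 0.0702, or adjusted p = 0.5 with an estimated correlation), with 0 genes passing over either set. They were called without low avidity 3 (adjusted p = 0.0319) and with array weights (adjusted p = 0.0349). Of the receptors of the TNF family, Tnfrsf4 (OX40) differed by 0.01 log2 (95% interval -0.32 to 0.34), Tnfrsf9 (4-1BB) by 0.41 (-0.04 to 0.85), Tnfrsf18 (GITR) by -0.12 (-0.49 to 0.25) and Cd27 by 0.16 (-0.14 to 0.46). Tnfrsf9 differed by 0.19, Tnfrsf4 by 0.13, Tnfrsf18 by -0.014 and Cd27 by 0.25 without high avidity 1. Tnfrsf4 was at 4.81 ± 0.16 (SD, n = 4) and 4.80 ± 0.23 (SD, n = 3), within the range of the background guide. Cd28 differed by 0.13 and Slamf6 by 0.48. The 18 inhibitory receptors had a mean of 0.08 log2 (camera, adjusted p = 0.0818, or adjusted p = 0.5 with an estimated correlation). They were called without low avidity 3 (adjusted p = 0.0407), with no filter (adjusted p = 0.0316) and with the mean of a gene's rows (adjusted p = 0.0325). No gene passed over either set: Nt5e (CD73) differed by 0.75, Btla by 0.41, Cd96 by 0.40, Cd200 by 0.31, Lag3 by 0.18 and Pdcd1 (PD-1) by -0.18.

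Negative regulators of T cell receptor signalling, a list that includes anergy genes, lay higher in low avidity cells, with a mean of 0.15 log2 over 35 genes, 21 of them higher (camera, adjusted p = 0.0102), or adjusted p = 0.5 with an estimated correlation, and adjusted p = 0.0518 without low avidity 1. Cbl, a ubiquitin ligase, rose adjusted over the list alone (0.60 log2, SE 0.12), 0 passed over all genes, and Tox differed by 0.71, Dusp2 by 0.54 and Nfatc1 by 0.39. The 31 early response genes had a mean of 0.15 log2 with 21 higher (camera, adjusted p = 0.0493), or adjusted p = 0.701 with an estimated correlation, and 0 passing over either set. Nr4a1 differed by 0.40 and Egr1 by 0.39, Myc by 0.40, and Jun by -0.58. High avidity 1 lay at -0.35 for this list, high avidity 2 and 3 at 0.03 and 0.07, and low avidity samples at 0.01 to 0.14. The call ended without high avidity 1 (mean 0.015, adjusted p = 0.539), without low avidity 1 (adjusted p = 0.164) and without low avidity 3 (adjusted p = 0.0539), and under 4 of the settings for filter, normalization and gene level (adjusted p of 0.0865 to 0.21) and with array weights (adjusted p = 0.0773). Activation markers Cd69, Cd44 and Cd5 differed by 0.26, -0.05 and 0.17, Cd69 with the opposite sign on its second row.

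Ribosomal protein and respiratory chain genes lay slightly lower in low avidity cells. Of 47 ribosomal protein genes 40 were lower, with a mean of -0.14 log2 (camera, adjusted p = 0.0065), or adjusted p = 0.701 with an estimated correlation. Rpl7a differed by -0.29, Rps23 by -0.28, Rpl24 by -0.24 and Rpl14 by -0.21, and the call ended without high avidity 3 (mean -0.07, adjusted p = 0.198) or low avidity 2 (adjusted p = 0.0557). Of 54 oxidative phosphorylation genes 39 were lower, with a mean of -0.12 log2 (camera, adjusted p = 0.0166), or adjusted p = 0.5 with an estimated correlation. Cox7b differed by -0.50, Cox6a1 and Ndufa3 by -0.49 and Cox7c by -0.41, and the call ended without high avidity 2 (adjusted p = 0.109) or low avidity 2 (adjusted p = 0.105), with no filter (adjusted p = 0.0604) and with an intensity trend (adjusted p = 0.087). A second row of Cox6a1, at a mean level of 8.33 against 8.37, differed by only -0.025, and the other rows of Cox7c by -0.40 to 0.018. No gene of either list passed, over all genes or adjusted over the list alone. Other lists were not called with the main settings and had 0 genes passing over either set unless named. The 20 glycolysis genes had a mean of -0.06 log2 (camera, adjusted p = 0.589), the 19 cholesterol synthesis genes -0.13 (adjusted p = 0.692), the 29 Myc-linked growth genes 0.05 (adjusted p = 0.161) and the 23 genes of the unfolded protein and heat shock response 0.015 (adjusted p = 0.397). Without high avidity 2 the last pair was called, both higher (means 0.13 and 0.11, adjusted p = 0.0165 and 0.0225). For these an estimated correlation over all samples gave adjusted p = 0.701 and 0.792. The 21 NF-kappaB genes had a mean of -0.017 and a median of 0.12 with the test on the higher side (adjusted p = 0.145, or adjusted p = 0.562 with an estimated correlation). They were called with no filter (adjusted p = 0.0316), and Birc3 rose adjusted over the list alone. The 16 interferon gamma response genes had a mean of 0.08 (adjusted p = 0.235) and the 28 type I interferon response genes 0.14 (adjusted p = 0.0835), among them Ddx58 (0.51) and Parp14 (0.38). The type I list was called without low avidity 1 (mean 0.34, adjusted p = 8.39e-05) and without high avidity 3 (0.33, adjusted p = 0.000943), and with no filter (adjusted p = 0.017). With each sample left out in turn, its mean ran from -0.034 to 0.34 (camera, adjusted p up to 0.947). An estimated correlation over all samples gave adjusted p = 0.739.

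Markers of CD8 T cells were well above background in all samples. Cd8a was at 9.94 ± 0.13 (SD, n = 4) and 9.69 ± 0.22 (SD, n = 3), and Cd8b1 at 9.36 ± 0.21 (SD, n = 4) and 9.06 ± 0.16 (SD, n = 3), in low and high avidity cells. The 16 CD8 T cell markers had a mean of 0.10 log2, 13 of them higher (camera, adjusted p = 0.0806), with Lat at 0.47 and Cd2 at 0.25. Without high avidity 1, which lay at 0.18 against -0.27 and -0.09 for high avidity 2 and 3, this list was called (mean 0.22, adjusted p = 0.00272, or adjusted p = 0.168 with an estimated correlation). It was also called with no filter (adjusted p = 0.017), the mean of a gene's rows (adjusted p = 0.0428) and array weights (adjusted p = 0.011). Over leaving out each sample its mean ran from -0.00043 to 0.22 (camera, adjusted p up to 0.634). An estimated correlation over all samples gave adjusted p = 0.701. The 10 NK cell markers had a mean of 0.20 (adjusted p = 0.0942), with Eomes passing adjusted over the list alone. They were also called without high avidity 1 (mean 0.36, adjusted p = 0.00667, or adjusted p = 0.168 with an estimated correlation) and with array weights (adjusted p = 0.0312). With each sample left out in turn, their mean ran from 0.089 to 0.36 (camera, adjusted p up to 0.499). An estimated correlation over all samples gave adjusted p = 0.701. Lists of other cells were not called with the main settings. These were 16 B cell markers (mean -0.03, adjusted p = 0.621), 19 macrophage markers (-0.07, adjusted p = 0.235), 14 dendritic cell markers (mean 0.001, median -0.10, adjusted p = 0.589), 12 stromal markers (-0.07, adjusted p = 0.238, or 0.0481 with no filter and 0.727 with an estimated correlation) and 9 red cell and platelet markers (0.24, adjusted p = 0.969). The 9 CD4 and regulatory T cell markers had a mean of 0.15 and a median of -0.12 with the test on the higher side (adjusted p = 0.941), which turned when samples were normalized again or centred (means 0.13 and 0.20). Ikzf2 rose adjusted over that list alone. The 7 neutrophil markers had a mean of 0.04 and a median of 0.0073 with the test on the lower side (adjusted p = 0.941), which turned under a second quantile normalization (mean 0.08).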

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

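The genes and lists named in the text were screened for single samples far from the others among the 4 low avidity samples, 117 genes and 35 lists in all, by the gap of the highest or lowest sample over the whole range. Chance marks about 1 in 20 such groups. Of the 104 genes that follow the rule and the 35 lists, 6 and 3 were marked, and the other marked values, Muc13 and Cdk1, belong to genes chosen after their values were seen. The 3 high avidity samples are too few for this screen. The progenitor list below was chosen after the single genes had been seen, and its test without members of other lists after the first result.

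Low avidity 1 held several genes of blood cells other than T cells. Car1, a carbonic anhydrase of red cell precursors, was at 8.94 there and at 3.98 to 4.77 in low avidity 2, 3 and 4, Mpo, the myeloperoxidase of myeloid precursors, at 6.03 against 3.79 to 3.97, and Muc13 at 6.04 against 3.95 to 3.98. The red cell and platelet list lay at 0.78 log2 above the mean of all samples, against -0.15 to -0.08. A few blood progenitors in the sorted sample may account for this: the mean change in low avidity 1 of the 22 of 30 listed progenitor genes that were in the fit lay at percentile 98.6 of 10000 random lists matched on expression, and that of the 19 in no other list at percentile 98.3, although these changes were small, 0.074 and 0.061 log2, and Elane (4.31) and Prtn3 (4.73), abundant in granulocyte precursors, were not raised. Members of the list went both ways against the mean of the other low avidity samples, from Kit (0.53 log2) and Slamf1 (0.48) to Tal1 (-0.22) and Cebpe (-0.38). Gata1 lay at 0.08, so the percentile does not speak for the list as a whole. Most members, such as Kit (4.82), Tal1 (4.27) and Gata1 (4.26), lay within the range of the background guide in low avidity 1. The percentile thus ranks small changes near background. Slamf1 and Tespa1 of that list are also expressed by T cells, and the sort of CD8+ T cells would be expected to remove progenitors. No biological explanation was tested.

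Other values in low avidity 1 were Cdk1 at 5.57 (4.70 to 4.72 in the other 3), Racgap1 at 7.46 (6.82 to 6.87), Il2 at 4.65 (4.86 to 4.89) and the Myc-linked growth list at 0.076 log2 above the mean of all samples (-0.0061 to 0.0073). In low avidity 2, Mcl1 was at 8.09 (7.85 to 7.89). In low avidity 3, the naive and memory T cell list lay at 0.23 (0.11 to 0.13). In low avidity 4, Ldhb was at 4.21 (3.85 to 3.89), near background.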

How the results depend on the processing

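The 3 genes that passed (2 higher, 1 lower, 3 of at least 2-fold) were the same 3 with no filter, a filter on 50% of genes, a second quantile normalization, median centring, the mean of a gene's rows, an intensity trend, robust eBayes and array weights, and no scaling moved the median of all genes by over 0.1 log2. With every row tested on its own, over 86872 rows, limma called 0 in each of these counts (5680 at an unadjusted p under 0.05); the adjusted p was 0.13 for each of the 3 genes, with its value as before, and the larger number of tests and a spread estimated over other rows enter together by construction. Leaving out each sample gave 0 to 93 genes, 0 to 26 higher, 0 to 67 lower and 0 to 64 of at least 2-fold, the highest in each case without high avidity 1. The 8 gene lists called became 13 with no filter, 11 with array weights, and 6 to 10 when each sample was left out, and 0 with an estimated correlation or with fry. The cause was not tested, except that fewer samples and other correlations enter by construction. Against the preset 0.01, the estimated correlation was 0.90 for mitosis, 0.66 for DNA replication and 0.31 for naive and memory T cells. It was 0.17 for receptor segments and ribosomal proteins, 0.14 for early response, 0.029 for oxidative phosphorylation and -0.014 for negative regulators. Where it lies well above the preset, the camera p-values at the preset come out too small. For negative regulators it lay below the preset, yet the unadjusted camera p went from 0.00175 to 0.0152 with the estimate. The size of the correlation therefore does not account for the loss of that call. Same-numbered samples did not deviate together (correlations of -0.029, -0.018 and 0.015), so the numbers gave no sign of pairing. A small effect shared by same-numbered samples could be missed by correlations over all genes. With the replicate block limma called 0 genes (0 higher, 0 lower, 0 of at least 2-fold, with 918 at an unadjusted p under 0.05) and 7 lists, and the early response list was lost (adjusted p = 0.0812). Low avidity 4 has no high avidity sample of the same number, so it adds nothing to the group difference in this fit. The differences are therefore those without low avidity 4, with the replicate numbers also fitted. Over the 17 alternatives of each list, adjusted p ran from 4.04e-34 to 0.701 for mitosis, 3.01e-21 to 0.701 for DNA replication, 8.14e-10 to 0.661 for naive and memory T cells, 3.55e-05 to 0.5 for receptor segments, 1.37e-05 to 0.5 for oxidative phosphorylation, 0.000178 to 0.701 for ribosomal proteins, 0.00175 to 0.5 for negative regulators, 0.00559 to 0.701 for early response, 0.00833 to 0.701 for cytokine receptors, 0.00272 to 0.701 for CD8 markers, 0.00667 to 0.701 for NK markers, 8.39e-05 to 0.947 for type I interferon response, 0.0319 to 0.5 for costimulatory and 0.0316 to 0.5 for inhibitory receptors, 0.0316 to 0.649 for NF-kappaB, 0.0165 to 0.983 for Myc-linked growth, 0.0225 to 0.986 for the unfolded protein response and 0.0481 to 0.833 for stromal markers. Over leaving out each sample, limma's adjusted p for Gzmb ran from 0.0409 to 0.845. Intensities near background, where levels of about 3.65 to 5.03 log2 lie in olfactory receptor genes, limit what can be said of dim genes.

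None of the values that turned had passed with the main settings. With the replicate block, as without low avidity 4, Tnfrsf4 was at -0.059, death receptors at -0.021, CD4 and regulatory T cell markers at 0.11 and neutrophil markers at 0.094. For lists the direction is that of the test. With no filter the death receptor list was at -0.021 and cholesterol synthesis at -0.13, with the filter on 50% of genes dendritic markers at 0.23, and with the mean of rows Cd69 at -0.41. A second quantile normalization put cytotoxic molecules at -0.092, CD4 and regulatory markers at 0.13 and neutrophil markers at 0.081, and median centring put Bcl2l1 at 0.017 and CD4 and regulatory markers at 0.20. Array weights put Cd44 at 0.023 and neutrophil markers at 0.064, and fry turned the red cell and platelet list (0.24). Leaving out each sample, genes ranged as follows: Cd69 -0.12 to 0.50, Mcl1 -0.043 to 0.29, Cd5 -0.013 to 0.30, Mki67 -1.82 to 0.15, Pcna -0.81 to 0.088, Prtn3 -0.034 to 0.043, Bcl2l1 -0.095 to 0.022, Il2 -0.16 to 0.024, Pdcd1 -0.40 to 0.057, Tnfrsf4 -0.10 to 0.13, Trav16 -0.090 to 2.05, Ctsg -0.060 to 0.31, Mpo -3.3e-05 to 0.75, Muc13 -0.079 to 0.62 and Cd44 -0.22 to 0.036. Of the 117 genes followed by name, 50 turned or moved by over 1.5 times when some sample was left out, and 0 of these had passed; others among them were Prf1 (-0.33 to -0.047), Cd28 (0.022 to 0.25), Cd2 (0.12 to 0.33), Btla (0.25 to 0.52) and Il2ra (-1.07 to -0.44). Lists ranged as follows: cytotoxic molecules -0.17 to 0.024, homing molecules -0.11 to -0.012, Myc-linked growth -0.034 to 0.13, unfolded protein response -0.13 to 0.11, neutrophil markers -0.059 to 0.094, cholesterol synthesis -0.32 to -0.0028, red cells and platelets 0.010 to 0.32, CD4 and regulatory markers 0.11 to 0.22, p53 targets -0.10 to -0.035 and death receptors -0.076 to 0.022. The cause was not tested.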

Other observations

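The tests of a swapped label, of mixed-in T cells and of quality, and the last permutation test below, were chosen after the values had been seen. Segments of the receptor differed among the high avidity samples. Trav16, an alpha chain segment, was at 7.98 in high avidity 1, 6.53 in high avidity 2 and 3.70, near background, in high avidity 3, and at 6.68 to 7.69 in the low avidity samples. Trav7n-4 was at 5.98, 5.40 and 4.68 in high avidity 1, 2 and 3. Irf4, a transcription factor induced by receptor signalling, was at 5.99 in high avidity 1 and at 9.65 and 9.44 in high avidity 2 and 3. The low avidity samples lay at 9.37 to 10.31. The difference between the groups was 1.48 log2 on this row, but -0.24 and 0.16 on the gene's 2 other rows. The brighter of these had a mean level of 8.57, so the other rows do not bear out a difference of that size.

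Type I interferon response genes varied between samples of 1 group. The mean of the 28 genes lay at -0.52 log2 in low avidity 1, 0.59 in low avidity 2, 0.08 in low avidity 3 and 0.10 in low avidity 4, and at -0.31, -0.24 and 0.30 in high avidity 1, 2 and 3. Without high avidity 1, genes outside the lists also passed limma, among them a pair picked after their values were seen: S100a4, a calcium-binding protein of effector and memory T cells, fell by 1.76 log2 (adjusted p = 0.0409), and Rasgrp1, an activator of Ras in T cells, rose by 1.23 log2 (adjusted p = 0.0411).

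High avidity 1 had mitosis genes 2.05 log2 (median -2.05) below high avidity 2 and 3. Of 10000 random lists of genes at the same levels the lowest median was -0.31, so genes at those levels did not fall as a whole. This cannot decide on a loss of array or RNA quality that lowers genes by their level. The quantile normalization within RMA gives the arrays like distributions and would largely remove such a loss beforehand. A loss that acts on other properties of a transcript was not tested. A low avidity sample under a high avidity label is argued against by Trav7n-4, which lay -2.96 log2 from the low avidity mean (SD 0.23). The gene came from a fit that counted high avidity 1 as high. It also passed without that sample (3.90 log2, limma, adjusted p = 0.00597). Trdv2-2 went with Trav7n-4, at 6.20 in high avidity 1 against 4.37 to 4.61 in the low avidity samples. The latter lie within the range of the background guide. Trdv2-2 also passed without high avidity 1 (-2.20 log2, limma, adjusted p = 0.00563). Trav16 went the other way, at 7.98 in high avidity 1 against 6.68 to 7.69 in the low avidity samples. The argument thus rests on the few genes that the fit picked. Resting T cells with another receptor mixed into the sample cannot be told apart from fewer dividing cells of the same kind. Trdv2-2 differed by -0.49 log2 from high avidity 2 and 3, and its level in other T cells was not measured. Trav16 (7.98 against 6.53 and 3.70) and Trav7n-4 (5.98 against 5.40 and 4.68) were higher in high avidity 1. The segment list lay above high avidity 2 and 3 by a mean of 0.53 and a median of 0.087 log2. High avidity 2 and 3 also differed from each other in both segments, so these values do not decide. A difference between animals or in the response to vaccination stays open, untested.

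Other splits of the 7 samples bear on the counts. For the genes that passed, 2 of the 35 splits, the real one included, gave as many as 3, and the highest other split gave 3 (high avidity 2 and 3 with low avidity 3), so chance cannot be excluded for the count. For gene lists, 8 of the 35 splits gave as many as 8 and the highest other gave 11, so chance cannot be excluded for that count either. Without high avidity 1, 1 of the 15 splits, the real one itself, gave as many as 93 genes, and the highest other gave 0; 15 splits are too few for a share under 0.05.

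Bcl6 and Cxcr5, both of follicular helper cells, differed by 1.05 and 1.36 log2, and a wider programme of that kind in low avidity cells was put forward as a hypothesis. Of 10 other genes of that programme, 4 of which also stand in other lists, 4 were higher and 6 lower in low avidity cells. The median difference was -0.075 log2, with p = 0.892 by camera and p = 0.4 by a two-sided exact permutation test over the 35 splits, the latter run after the camera result was seen. The prediction written before the test was a camera p under 0.05 on the higher side if the programme was shared. If it was not, a median difference that was not positive was predicted, and this was met. A list of any kind would often meet this, as the median difference over all genes was -0.032 log2. Meeting it therefore tells little. The camera prediction was not met, and the list gave no sign of a wider programme. The median lies within the spread of the 10 differences (MAD 0.23), a limit that was not part of the prediction, and the members go both ways. A small shift is therefore not excluded.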
